A study of Homo sapiens with 8 samples.

How the data were processed

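RNA was sequenced from HCT116 cells, a human colon cancer line, and from a derived line with a knockout (KO) of FBXW7, the substrate receptor of an SCF ubiquitin ligase. Per the labels' protocols, cells were heated at 42 °C for 1 h and sampled, or were then returned to 37 °C for 2 h and sampled. The 4 groups are wild-type (WT) heat shock, WT recovery, KO heat shock and KO recovery, each with 2 libraries that the series design text calls biological replicates. Whether the replicates came from separately grown cultures or separate KO clones is not given in the sources used here, so p-values measure only the spread between these libraries. Unheated samples at 37 °C were not analysed here. Per the labels' protocols, poly-A selected or ribosomal RNA depleted RNA was used, libraries were made strand-specific with the dUTP method, and 50-base single reads were sequenced on an Illumina HiSeq instrument. Which of the 2 kinds of RNA each library was made from is not given in the sources used here.

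The submitters' processing notes name CASAVA, TopHat and the human build hg19, without versions or roles. The program that counted reads per gene and its strand setting are not given in the sources used here, so reads from a gene and from a gene overlapping it on the other strand may not have been told apart. The authors deposited 4 comparison tables, 1 per replicate and cell line. Per the file headers, each holds for 55075 Ensembl genes the read counts of 2 libraries, a log2 fold change normalized by the column totals, and a Benjamini-Hochberg q-value. The layout is that of the DEGexp function of DEGseq. The deposited counts are whole numbers that were not normalized, and their totals differ between libraries. Which of the count columns is the recovery library rests on the order of names in each comparison and on the direction of the authors' log2 fold change, and no column name states it. If that order were wrong, every recovery change below would change sign. Genes given as NA in both columns had no read in either library and were set to 0.

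Total counts were 20248480 and 19979779 in the WT heat shock libraries and 15507896 and 15654696 in the WT recovery libraries. The KO heat shock libraries held 26102649 and 34387618 counts, and the KO recovery libraries 24531569 and 27187797. Reads were seen for 32200 genes. Counts carry no molecular identifiers, so counting intervals and floors cover counting error only. Replicates correlated at r = 0.991 to 0.995 across genes on the log2 scale, and their counts differed by more than sampling noise, with a chi-square per degree of freedom of 19.6 in WT heat shock, 2.48 in WT recovery, 5.19 in KO heat shock and 8.59 in KO recovery. No pair of replicates was therefore treated as 1 library.

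Counts were tested with the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3, after filtering with filterByExpr, which left 17471 genes, and TMM scaling. All 8 libraries entered each fit. Recovery was compared with heat shock within matched pairs (same cell line and replicate number), as the series design text describes, with 2 residual degrees of freedom, and the difference of the 2 recovery responses was the interaction in that model. Deviations of same-numbered libraries from their group means were uncorrelated across genes, with r = -0.0156 in WT and -0.0138 in KO. KO was compared with WT at each condition without a block, with 4 residual degrees of freedom. P-values were adjusted by the Benjamini-Hochberg method, and a gene passed at an adjusted p under 0.05. Errors given as ± beside a log2 fold change are standard errors obtained from the fold change and its F statistic, with 2 libraries per group. Levels are given as CPM, computed here from the deposited counts with TMM-scaled library sizes.

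The comparisons, tests and alternatives, a total of 26 gene lists, and the rule for naming genes were fixed before the data were examined. By that rule, the text may name for each comparison the 10 genes with the largest change in each direction that passed the test, had a mean count of at least 50, and changed the same way in both pairs (or, between lines, had no overlap of CPM). It also takes FBXW7, HSF1, HSF2, MYC, JUN and CCNE1 whatever their values, and up to 4 members of each list with the lowest p. Clone names and small RNA classes were not named. Y-linked genes and XIST were not named either, a limit that the fixed rule did not state. Of these, 19 were called between the lines at heat shock and 21 at recovery. Some genes that the rule takes are not reported here. The lists cover heat shock chaperones (cytosolic apart from the mitochondrial HSPD1 and HSPE1 and the ER protein SERPINH1), the CCT chaperonin and prefoldin, immediate early genes, the ER unfolded protein response, ATF4 and CHOP targets, p53 targets, transcripts of FBXW7 substrates, ribosome biogenesis, cholesterol biosynthesis and SREBP targets, mitotic genes, G1/S and replication genes, replication-dependent histones, abundant non-polyadenylated RNAs, proteasome subunits, NRF2 and oxidative stress genes, NF-kappaB targets, Notch targets, splicing kinases and SR proteins, ubiquitin genes, cytosolic ribosomal proteins, mitochondrially encoded genes, nuclear oxidative phosphorylation genes, glycolysis and hypoxia genes, epithelial and colon identity, mesenchymal and fibroblast markers, and immune and erythroid markers. Some genes stand on several lists. Lists were matched by symbol, and the mitochondrially encoded list was also tested without 1 entry that proved to be a nuclear pseudogene, a choice made after seeing the data. Lists with at least 5 tested genes (25 of 26) were tested with camera of limma 3.58.1 at a preset inter-gene correlation of 0.01, and p-values were adjusted over the 25 lists. Camera was repeated with an estimated correlation, and fry was run as a test of whether a list's genes move on balance in 1 direction.

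Settings varied in the fits were other replicate blocks, RLE and upper-quartile scaling, no low-count filter, a filter at a mean count of 50, DESeq2 1.42.0, an adjusted p under 0.01, a minimum fold change of 1.5, a fit within each cell line, and leaving out each library in turn. Leaving out 1 library of a matched pair also takes its partner out of the recovery estimates. The fits without either library of a pair are therefore not separate checks of a recovery response. Further settings were added after seeing the data: offsets that remove each library's smooth trends on GC content and transcript length, and a restriction to coding genes with a transcript of at least 1500 bases. Length and GC content came from GENCODE 29 on GRCh38, to which 48932 of the 55075 identifiers (88.8%) matched. The transcript that stands for a gene was redefined after results had been seen, first as the longest coding transcript, then in a trial as the median coding transcript, and at last as the median over the annotation's principal transcripts. The offsets were run under the first and the last definition. GRCh38 was used only for gene types, lengths, GC content and positions, and the positions given are GRCh38 positions.

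The fits were tested on simulated counts with the real depths and genes changed by known folds, 66 or 67 per fold size. Each gene had 1 mean and 1 spread for all libraries, without pair effects, and changed genes had a mean count of at least 50. As many genes were raised as lowered. The shares below need not hold in the data, where 41.8% to 63.1% of tested genes were called. Of genes changed 1.5-fold, 70.1% were recovered in WT recovery, 79.1% in KO recovery, 23.9% in the difference of responses, 83.6% in KO against WT at heat shock and 77.6% at recovery. Of genes changed 2-fold, the shares recovered were 97.0%, 100%, 88.1%, 95.5% and 94.0% in the same order. Unchanged genes made up 6.35%, 7.92%, 9.62%, 8.37% and 6.22% of the calls. On simulated GC trends between libraries, the offsets lowered the number of calls from 6256 to 9. That simulation held no true changes, so it cannot show whether the offsets spare real ones.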

Results

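RNA-seq read counts per gene were compared in 8 libraries of HCT116 colon cancer cells, 2 each from wild-type (WT) and FBXW7 knockout (KO) cells at the end of heat shock and after 2 h of recovery. FBXW7 marks proteins for degradation, and its known substrates include HSF1, the main transcription factor of the heat shock response, and MYC, JUN and cyclin E. The layout gave 5 comparisons: the recovery response in each line, the difference of these responses, and KO against WT at each condition. Total counts per library ran from 15507896 to 34387618, and 17471 genes were tested. Adjusted p-values for genes came from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, and those for gene lists from camera. Values after ± are standard errors of log2 fold changes unless given as SD, with n = 2 libraries per group. Genes said to have changed did so in the same direction in both replicate pairs, or between the lines had no overlap of CPM, unless stated otherwise. Where 5 or fewer members of a list moved in a direction, those outside the naming rule were chosen after their values were seen. Where a list's counts are given without those adjusted over the list alone, both were equal.

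FBXW7 (ENSG00000109670, chromosome 4, 152320544 to 152536063 in GRCh38) was lower in all 4 KO libraries than in all 4 WT libraries. At heat shock its level was 16.2 ± 1.74 CPM (SD, n = 2) in KO and 32.5 ± 1.47 CPM in WT cells, a log2 difference of -1.01 ± 0.10 (adjusted p = 1.9e-06). At recovery it was 13.9 ± 0.164 CPM in KO and 22.3 ± 0.892 CPM in WT cells, a log2 difference of -0.68 ± 0.11 (adjusted p = 8.0e-05). When the difference at recovery was tested against a minimum fold change of 1.5 it did not pass (adjusted p = 0.193). Counts summed over a gene cannot show which part of it was deleted. During recovery FBXW7 fell by 0.54 ± 0.11 on the log2 scale in WT cells (adjusted p = 4.1e-04). Its change in KO cells was -0.21 ± 0.11 (adjusted p = 0.135), and the difference of the responses was 0.33 ± 0.15 (adjusted p = 0.0801).

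The first comparison followed WT cells from the end of heat shock into recovery. Heat shock chaperones, which hold and refold damaged proteins, fell. HSPA1B, an inducible HSP70 (ENSG00000204388, chromosome 6, 31827735 to 31830255 in GRCh38), went from 167 ± 68.2 CPM (SD, n = 2) to 23.2 ± 4.56 CPM, a log2 change of -2.81 ± 0.12 (adjusted p = 1.2e-11). The HSP40 co-chaperones DNAJB1 and DNAJA1 fell by 1.91 ± 0.11 and 1.61 ± 0.10, and BAG3, a nucleotide exchange factor of HSP70, fell by 1.58 ± 0.12. Of 38 measured chaperone genes, 25 fell, 1 rose and 12 did not pass, against 26 and 1 adjusted over the list alone. The median change was -0.51 (adjusted p = 2.8e-09, and adjusted p = 0.599 with an estimated correlation). The gene that rose was ST13 (0.55 ± 0.10), an HSP70-interacting co-chaperone. HSPA1B has a near-identical copy, HSPA1A, that was counted at 1.49 CPM at heat shock and 0.271 CPM at recovery, so the split of reads between them is uncertain. Of the regulators reported in each comparison, HSF1 fell by 0.41 ± 0.10, HSF2 rose by 0.67 ± 0.11, MYC fell by 1.59 ± 0.10 and CCNE1, encoding cyclin E1, fell by 0.58 ± 0.10. HSF1 did not pass with GC and length offsets (-0.11, adjusted p = 0.222). JUN gave -0.05 ± 0.16 (adjusted p = 0.797), a value that turned on the replicate pair. It was 0.39 without WT heat shock replicate 1 and 0.40 without WT recovery replicate 1. Without WT heat shock replicate 2 or WT recovery replicate 2 it was -0.51. Each of these values rests on 1 WT pair.

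Genes of DNA replication, ribosome biogenesis, cholesterol synthesis and splicing fell in the same cells. Of 38 G1/S and replication genes, 35 fell and 0 rose (36 and 0 adjusted over the list alone), with a median of -0.81 (adjusted p = 1.3e-20, and adjusted p = 0.371 with an estimated correlation). They included CDC25A (-1.84 ± 0.11), a phosphatase that activates CDK2, UHRF1 (-1.47 ± 0.10), and MCM2 (-1.37 ± 0.10), a subunit of the replicative helicase. Of 35 ribosome biogenesis genes, 29 fell and 2 rose (29 and 2 adjusted over the list alone), with a median of -0.56 (adjusted p = 6.8e-13, and adjusted p = 0.371 with an estimated correlation). URB2 fell by 1.93 ± 0.10, GRWD1 by 1.75 ± 0.10 and PPAN by 1.60 ± 0.10, while GAR1 (0.38 ± 0.12) and GNL3 (0.34 ± 0.10) rose. Of 29 cholesterol biosynthesis and SREBP target genes, 20 fell and 3 rose, the same adjusted over the list alone (median -0.49, adjusted p = 6.1e-05, and adjusted p = 0.371 with an estimated correlation). NSDHL fell by 1.24 ± 0.12, MVD by 1.15 ± 0.11 and EBP by 0.97 ± 0.09, and CYP51A1, STARD4 and SCD rose by 0.48, 0.33 and 0.32. Of 20 splicing kinase and SR protein genes, 13 fell and 3 rose (15 and 3 adjusted over the list alone; median -0.48, adjusted p = 4.3e-05, and adjusted p = 0.371 with an estimated correlation). SRSF7 (-1.51 ± 0.11) and TRA2A (-1.11 ± 0.10) were among those that fell, and the kinases CLK3, SRPK1 and SRPK2 were those that rose.

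The lists of the ER unfolded protein response, proteasome subunits and mitotic genes moved down as well. Of 25 genes of the ER unfolded protein response, 11 fell and 5 rose (12 and 5 adjusted over the list alone), with a median of -0.19 (adjusted p = 0.00110, and adjusted p = 0.371 with an estimated correlation). HERPUD1, a part of ER-associated degradation, fell from 169 to 27.3 CPM, a log2 change of -2.63 ± 0.11, and SDF2L1 (-2.02 ± 0.14), DNAJB9 (-1.83 ± 0.12) and XBP1 (-1.33 ± 0.10) fell as well. HSP90B1, EDEM1, ERN1, ERO1LB and SEC61B rose by 0.30 to 0.98. Without WT heat shock replicate 2 this list no longer passed (adjusted p = 0.0644). Of 32 proteasome subunits, 22 fell and 2 rose, the same adjusted over the list alone (median -0.43, adjusted p = 7.7e-05, and adjusted p = 0.629 with an estimated correlation). PSMD4 fell by 1.09 ± 0.11 and PSMC3 by 1.05 ± 0.11, and PSMA4 and PSMC6 rose by 0.25 each. Of 38 mitotic genes, 18 fell and 7 rose, the same adjusted over the list alone (median -0.17, adjusted p = 0.0237, and adjusted p = 0.629 with an estimated correlation). PLK1 fell by 1.32 ± 0.11 and CDCA8 by 1.12 ± 0.09. The mitotic list failed in 5 of 16 other settings, among them leaving out WT heat shock replicate 2 (adjusted p = 0.262) or WT recovery replicate 2 (adjusted p = 0.280).

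Among the lists of signalling and stress genes, that of NF-kappaB targets passed in WT recovery, and the immediate early, ATF4 and CHOP, p53, glycolysis and hypoxia and Notch lists did not. Of 21 NF-kappaB targets, 9 rose and 4 fell, the same adjusted over the list alone (median 0.21, adjusted p = 0.0346, and adjusted p = 0.629 with an estimated correlation). BIRC3, an inhibitor of apoptosis, rose by 2.53 ± 0.15, BCL3 by 1.32 ± 0.13 and BIRC2 by 0.82 ± 0.10, while NFKBIB, TNFAIP2, NFKB1 and SOD2 fell by 0.55, 0.31, 0.29 and 0.26. This list failed in 8 of 16 other settings, 6 of them leaving out a library, with an adjusted p of up to 0.390. Of 41 immediate early genes, 14 rose and 9 fell (14 and 9 adjusted over the list alone), and the list did not pass (adjusted p = 0.155), although GADD45A (1.66 ± 0.10), BTG1 (1.37 ± 0.11) and ZFP36 (1.16 ± 0.10) rose. Among 27 ATF4 and CHOP targets 9 rose and 5 fell (adjusted p = 0.338): DDIT4, an inhibitor of mTORC1, rose by 1.69 ± 0.09 and DDIT3, encoding CHOP, by 0.91 ± 0.10, whereas CHAC1 fell by 1.17 ± 0.11 and ATF4 by 0.73 ± 0.10, as did ATF5, SLC7A5 and SLC3A2. Among 30 p53 targets 13 rose and 9 fell (15 and 9 adjusted over the list alone; adjusted p = 0.155), with GDF15 up by 1.23 ± 0.10 and AEN down by 1.61 ± 0.10. The hypoxia genes ANKRD37 and ADM rose by 1.82 ± 0.13 and 1.66 ± 0.13 in a glycolysis and hypoxia list with 12 of 30 genes up and 13 down, whose median (-0.11) and mean (0.15) differ in sign (camera upward, adjusted p = 0.338). Of 11 Notch targets 5 rose and 2 fell (adjusted p = 0.706), namely HES1 (1.63 ± 0.13), HEY1, NRARP, NOTCH3 and CDKN1A against MYC and CCND1.

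The other lists did not pass in WT recovery. Of 28 transcripts of FBXW7 substrates, 5 rose and 12 fell (adjusted p = 0.280). JUNB, NFKB2, XRCC4, BRAF and NFATC2 were those that rose. Of 52 cytosolic ribosomal protein genes 3 rose (RPL15, RPL22 and RPS25) and 17 fell (3 and 16 adjusted over the list alone; adjusted p = 0.251). Of 33 nuclear oxidative phosphorylation genes 6 rose and 13 fell (6 and 14 adjusted over the list alone; adjusted p = 0.307), and of 14 CCT chaperonin and prefoldin genes 2 rose (PFDN4 and VBP1) and 7 fell (adjusted p = 0.338). Of 14 ubiquitin genes 6 rose and 5 fell (adjusted p = 0.768), with UBB, STUB1 and ZFAND2A among those that fell. NRF2 and oxidative stress genes gave 6 up and 9 down of 24 (adjusted p = 0.726). Among 28 replication-dependent histones 2 rose (HIST1H2BD and HIST1H2BK) and 7 fell (0 and 2 adjusted over the list alone; adjusted p = 0.502). Of 10 abundant non-polyadenylated RNAs 3 fell, RN7SK, RMRP and SCARNA12 (adjusted p = 0.311). On the mitochondrially encoded list MT-ND3 and MT-ND6 rose and MT-CO2 and MT-CYB fell (adjusted p = 0.852). Of its 13 measured entries 1, under the symbol MT-ATP8, is by its identifier a processed pseudogene on chromosome 2, and without it the adjusted p was 0.694. With that entry the list's median and mean differ in sign in all comparisons but KO against WT at heat shock, and without it they have the same sign in all 5. In epithelial and colon identity 5 of 13 genes rose (EPCAM, CDH1, CLDN3, CLDN4 and ESRP1) and 5 fell (KRT8, KRT18, KRT19, CDX2 and AXIN2; adjusted p = 0.662). Of 9 mesenchymal and fibroblast markers TWIST1 rose and VIM fell (adjusted p = 0.790). Without WT heat shock replicate 1 or WT recovery replicate 1, HIST1H2BK, SCARNA12, VIM and MT-ND6 did not pass, nor did HIST1H2BD and MT-CYB without WT heat shock replicate 2 or WT recovery replicate 2 (adjusted p of 0.0626 to 0.478). Of 3 measured immune and erythroid markers, too few for a list test, CD68 fell by 0.56 ± 0.12. Median and mean also differ in sign for the ubiquitin and mesenchymal lists.

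In total 4334 genes rose and 4540 fell in WT recovery, 1478 and 658 of them at least 2-fold. Under upper-quartile scaling the split was 5303 higher and 3686 lower, with the median of all genes shifted to 0.10, so changes smaller than this are relative to the scaling. Of the 10 largest rises, all but ZNF90 and EDARADD were processed pseudogenes, led by PPIAP22 (5.45 ± 0.27), EEF1A1P5 (4.81 ± 0.23) and ANXA2P2 (4.71 ± 0.23), and those exceptions overlap pseudogenes. Such copies share sequence with their parent genes, and their values are uncertain. Processed pseudogenes took 0.880% ± 0.0850 (SD, n = 2) of counts in WT recovery, 0.608% ± 0.187 in WT heat shock, 0.277% ± 0.0614 in KO heat shock and 0.639% ± 0.0239 in KO recovery. Among the largest falls, ID2, an inhibitor of helix-loop-helix factors, changed by -2.09 ± 0.10 and TUBB4B, a beta-tubulin, by -2.05 ± 0.11. FAM166A (-2.63 ± 0.11) overlaps TUBB4B on the other strand, and some of its counts may be of TUBB4B where strand was not used in counting. In KO recovery FAM166A changed by 2.41 and TUBB4B by 0.33. Whether the share of such reads differed between libraries was not measured.

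**Figure D1:**
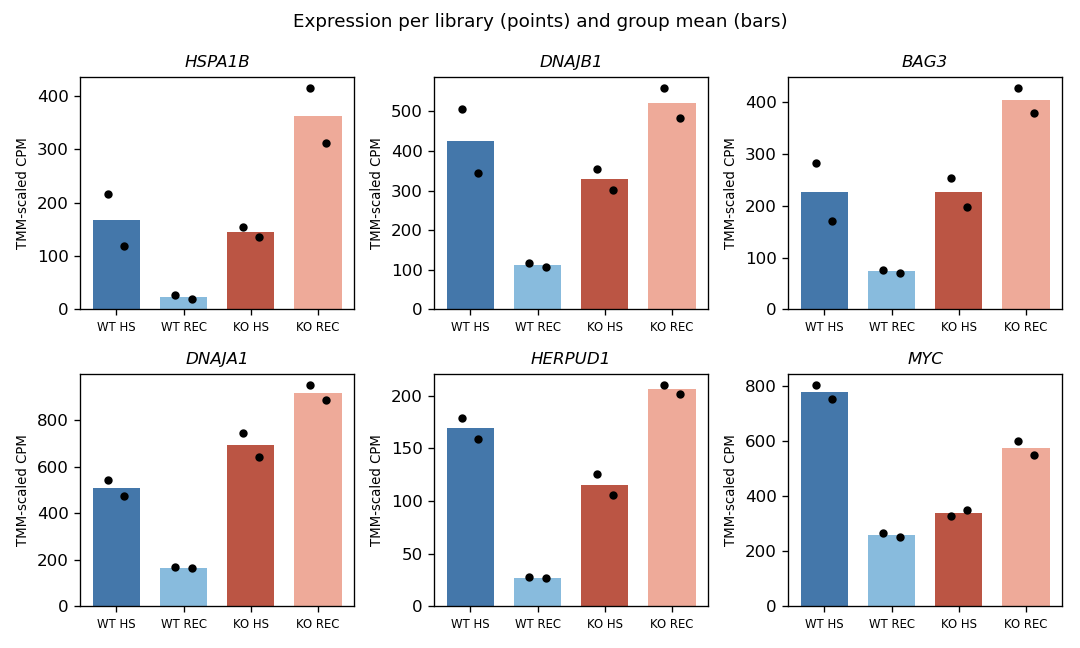
TMM-scaled CPM of HSPA1B, DNAJB1, BAG3, DNAJA1, HERPUD1 and MYC in each library, with points for libraries and bars for the means of 2 libraries per group. In WT cells the mean of HSPA1B was 167 at heat shock and 23.2 at recovery, and in KO cells 145 and 363.

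The next comparison covered the same interval in the KO line. Heat shock chaperones rose: HSPA1B went from 145 ± 12.2 CPM (SD, n = 2) to 363 ± 72.5 CPM, a log2 change of 1.31 ± 0.11 (adjusted p = 2.8e-08). HSPE1, the mitochondrial HSP10, rose by 1.40 ± 0.10, SERPINH1, a collagen chaperone of the ER, by 1.38 ± 0.14 and HSPB1, a small heat shock protein, by 0.91 ± 0.11. Of 38 chaperone genes 19 rose and 1 fell (19 and 2 adjusted over the list alone), with a median of 0.30 (adjusted p = 8.8e-05, and adjusted p = 0.529 with an estimated correlation). The gene that fell was FKBP5 (-0.42 ± 0.09). The list was fixed as one of cytosolic chaperones, but HSPE1 and its partner HSPD1 act in mitochondria and SERPINH1 in the ER. HSPE1 and HSPB1 have transcripts of 950 and 909 bases. Over 629 coding genes of 600 to 1000 bases the median change in KO recovery was 0.40. The transcripts of HSPA1B (2521 bases) and SERPINH1 (2299 bases) are longer. Immediate early genes, which respond to growth factor and stress signals, rose in 29 of 41 cases with 0 falling (30 and 0 adjusted over the list alone; median 0.60, adjusted p = 2.8e-19, and adjusted p = 0.416 with an estimated correlation). EGR1 went from 126 to 688 CPM, a log2 change of 2.45 ± 0.11, DUSP5, an ERK phosphatase, rose by 2.23 ± 0.11 and IER2 by 1.55 ± 0.10. HSF1 rose by 0.29 ± 0.10, MYC by 0.76 ± 0.10, JUN by 0.60 ± 0.16 and CCNE1 by 0.41 ± 0.09, and HSF2 fell by 0.44 ± 0.10. HSF1 and HSF2 did not pass with GC and length offsets (-0.02 and -0.13), nor when either KO pair lost a library. CCNE1 did not pass without KO heat shock replicate 1 or KO recovery replicate 1, and JUN did not pass without KO heat shock replicate 1.

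Genes of the integrated stress response and ER stress rose. Of 27 ATF4 and CHOP targets 15 rose and 1, SLC7A11 (-0.28 ± 0.10), fell, the same adjusted over the list alone (median 0.34, adjusted p = 2.3e-05, and adjusted p = 0.416 with an estimated correlation). DDIT3 rose by 1.85 ± 0.11, DDIT4 by 1.84 ± 0.10 and TRIB3 by 1.31 ± 0.10. Of 25 ER unfolded protein response genes 12 rose and 1, ERO1LB (-0.65 ± 0.15), fell (13 and 2 adjusted over the list alone; median 0.23, adjusted p = 0.00522, and adjusted p = 0.436 with an estimated correlation). DERL3 rose by 2.65 ± 0.28, SDF2L1 by 1.52 ± 0.13 and HERPUD1 by 0.84 ± 0.09. Without KO recovery replicate 2 this list no longer passed (adjusted p = 0.0504). Of 32 proteasome subunits 18 rose and 3 fell, the same adjusted over the list alone (median 0.32, adjusted p = 2.4e-04, and adjusted p = 0.599 with an estimated correlation). PSMC1 rose by 1.25 ± 0.11 and PSMA7 by 1.14 ± 0.10, while PSMA4, PSMD5 and PSMD12 fell by 0.31, 0.48 and 0.26. DDIT3, DERL3, SDF2L1 and PSMA7 have transcripts of 600 to 1000 bases, a range with a median change of 0.40. So do FTL, FTH1 and NHP2, named below, while those of DDIT4, TRIB3, HERPUD1 and PSMC1 are longer. Of 24 NRF2 and oxidative stress genes 10 rose, with FTL and FTH1, the ferritin chains, up by 0.94 ± 0.11 and 0.86 ± 0.10, and GCLM, GCLC and SLC7A11 fell (median 0.15, adjusted p = 0.0496, and adjusted p = 0.599 with an estimated correlation; 8 of 16 other settings lost the call).

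Transcripts of cytosolic ribosomal proteins and of nuclear oxidative phosphorylation genes rose in KO recovery. Of 52 cytosolic ribosomal protein genes 47 rose and 1, RPSA (-0.46 ± 0.10), fell (48 and 1 adjusted over the list alone; median 0.90, adjusted p = 1.1e-39, and adjusted p = 0.416 with an estimated correlation). RPS27 went from 2.42 to 44.3 CPM, a log2 change of 4.21 ± 0.13, and RPS28 from 16.9 to 281 CPM, a log2 change of 4.05 ± 0.14. RPS21 rose by 2.15 ± 0.12 and RPL37 by 1.91 ± 0.11. Of 33 nuclear oxidative phosphorylation genes 23 rose and 4 (NDUFB5, NDUFV2, SDHD and UQCRB) fell (24 and 4 adjusted over the list alone; median 0.39, adjusted p = 5.0e-07, and adjusted p = 0.525 with an estimated correlation). NDUFA1 and NDUFA2, complex I subunits, rose by 2.12 ± 0.11 and 1.49 ± 0.11, and COX6C, of complex IV, by 1.64 ± 0.12. The median transcript of the ribosomal protein list was 844 bases long, and between these libraries the median change was 0.71 over 125 coding genes of 400 to 600 bases but -0.02 over 18 under 400 bases, RPS27 and RPS21 among them. Mitochondrial tRNA took 0.0438% ± 9.4e-04 (SD, n = 2) of counts in KO heat shock and 0.547% ± 0.107 in KO recovery, against 0.499% ± 0.173 and 0.412% ± 0.0222 in WT heat shock and recovery. Whether the KO heat shock libraries were made from the same kind of RNA as the others, poly-A selected or depleted of ribosomal RNA, is not given in the sources used here, and they enter KO recovery, the difference of responses and KO against WT at heat shock.

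The lists of mitotic genes and of abundant non-polyadenylated RNAs moved down in KO recovery. Of 38 mitotic genes 21 fell and 3 (PLK1, AURKB and CDC20) rose (25 and 4 adjusted over the list alone; median -0.40, adjusted p = 9.0e-06, and adjusted p = 0.499 with an estimated correlation). ASPM fell by 1.00 ± 0.11, CENPE, a kinetochore motor, by 0.95 ± 0.10 and KIF11, a spindle motor, by 0.88 ± 0.09. Of 10 abundant non-polyadenylated RNAs 6 fell and RN7SL1 rose (the same adjusted over the list alone; median -1.27, adjusted p = 0.0105, and adjusted p = 0.436 with an estimated correlation). RPPH1, the RNA of RNase P, changed by -2.10 ± 0.25 and -1.96 ± 0.24 under its 2 identifiers, which count as 2 of the 6, RMRP by -1.63 ± 0.20 and RN7SK by -1.49 ± 0.20. At heat shock these 10 RNAs had a median difference of 1.16 between KO and WT libraries, and whether the KO heat shock libraries were poly-A selected, which would lower such RNAs, is not given in the sources used here. The call in KO recovery failed in 4 of 15 other settings, 3 of them leaving out a KO library, with an adjusted p of up to 0.156. Ribosome biogenesis genes rose in 14 of 35 cases and fell in 5, NOP58, RRP1B, GAR1, UTP15 and DDX21 (17 and 6 adjusted over the list alone; median 0.20, adjusted p = 0.0314, and adjusted p = 0.436 with an estimated correlation), with NHP2 up by 1.70 ± 0.10 and 5 of 16 other settings without the call. Glycolysis and hypoxia genes rose in 16 of 30 cases and fell in 5, BNIP3L, P4HA1, EGLN3, KDM3A and ERO1L (17 and 6 adjusted over the list alone; median 0.28, adjusted p = 0.0470, and adjusted p = 0.695 with an estimated correlation). BHLHE40 rose by 1.65 ± 0.09, and 6 of 16 other settings lost the list's call.

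In total 3601 genes rose and 3694 fell in KO recovery, 745 and 421 of them at least 2-fold. This count of 7295 was 4789 with DESeq2, 2838 without KO heat shock replicate 1, 4555 without KO heat shock replicate 2, 3245 without KO recovery replicate 1 and 4654 without KO recovery replicate 2. Several of the genes that rose most lie beside or across a gene on the other strand: OVOL3 overlaps POLR2I, WDR38 (5.69 ± 0.18) overlaps RPL35, PHOX2A (3.81 ± 0.35) overlaps INPPL1, NAALADL1 (3.60 ± 0.27) overlaps SAC3D1, SNHG9 (3.91 ± 0.17) lies within 1 kb of RPS2 and IFFO1 (3.77 ± 0.36) within 1 kb of GAPDH. These neighbours changed by less, POLR2I by 1.70, RPL35 by 0.86, INPPL1 by 0.11, SAC3D1 by 0.81, RPS2 by 1.26 and GAPDH by 0.22, and the share of their reads in the counts was not measured. RPS28 overlaps NDUFA7, which changed by 0.76, and MTND1P23 (6.30 ± 0.27) is a nuclear copy of a mitochondrial gene, whose value is uncertain. The largest falls were mainly of pseudogenes, led by EEF1A1P11 (-3.16 ± 0.29), RPL9P9 (-3.04 ± 0.29) and RPS2P7 (-2.79 ± 0.33). The median change of 367 processed pseudogenes with a named parent was -0.38. Yet the share of counts in processed pseudogenes was 0.277% in KO heat shock and 0.639% in KO recovery. Why the share and the median differ in direction was not tested. For the p53, NF-kappaB, Notch, epithelial and mesenchymal lists, none of which passed, median and mean differ in sign.

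The difference of the recovery responses, KO minus WT, was tested directly as the interaction. Among the chaperones with the lowest p it was 4.12 ± 0.16 for HSPA1B (adjusted p = 1.4e-12), 2.57 ± 0.15 for DNAJB1, 2.43 ± 0.17 for BAG3 and 2.02 ± 0.14 for DNAJA1. Of 38 chaperone genes, 26 had a higher response in KO cells and 3 (FKBP5, PTGES3 and ST13) a lower one, the same adjusted over the list alone (median 1.04, adjusted p = 1.9e-09, and adjusted p = 0.452 with an estimated correlation). HERPUD1 (3.46 ± 0.14), SDF2L1 (3.54 ± 0.19) and HSPA5 (1.67 ± 0.14), the ER HSP70, were on the ER unfolded protein response list, with 15 of 25 genes higher and HSP90B1, CANX, ERN1 and ERO1LB lower (median 0.60, adjusted p = 2.0e-04, and adjusted p = 0.452 with an estimated correlation). Ribosome biogenesis had 22 of 35 genes higher, with PPAN at 2.49 ± 0.14 and NHP2 at 2.21 ± 0.15, and GAR1, GNL3 and DDX21 lower (median 1.05, adjusted p = 2.6e-09, and adjusted p = 0.452 with an estimated correlation). G1/S and replication had 31 of 38 genes higher, with UHRF1 at 1.98 ± 0.14 and MCM2 at 1.95 ± 0.15, and 1 lower (median 0.93, adjusted p = 1.5e-09, and adjusted p = 0.452 with an estimated correlation). Immediate early genes had 23 of 41 higher and 6 lower, with DUSP2, an ERK phosphatase, at 3.30 ± 0.20, EGR1 at 2.68 ± 0.15 and GADD45A at -1.66 ± 0.14 (median 0.43, adjusted p = 4.7e-04, and adjusted p = 0.452 with an estimated correlation). Counts for these lists were unchanged when adjusted over the list alone. SDF2L1 and NHP2 have transcripts of 865 bases each, and coding genes of 600 to 1000 bases had a median difference of 0.65. With GC and length offsets the immediate early list did not pass (adjusted p = 0.0596) and its median was -0.04.

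The response was also higher in KO cells for cholesterol, proteasome, splicing, ribosomal protein and respiration genes. NSDHL differed by 1.85 ± 0.16 in the cholesterol and SREBP list, where 17 of 29 genes were higher and 6 lower (median 0.50, adjusted p = 7.1e-04, and adjusted p = 0.452 with an estimated correlation). PSMD4 differed by 2.07 ± 0.16 among 22 of 32 proteasome subunits that were higher, with PSMA4 and PSMD5 lower (median 0.79, adjusted p = 4.9e-06, and adjusted p = 0.581 with an estimated correlation). SRSF7 differed by 2.35 ± 0.15 among 14 of 20 splicing genes that were higher, with SRPK1 and SRPK2 lower (16 and 2 adjusted over the list alone; median 0.59, adjusted p = 0.00251, and adjusted p = 0.452 with an estimated correlation). RPS21 differed by 2.71 ± 0.16 and RPL37 by 2.17 ± 0.15 among 42 of 52 ribosomal protein genes that were higher, with RPL15, RPL22 and RPSA lower (43 and 3 adjusted over the list alone; median 1.11, adjusted p = 8.8e-17, and adjusted p = 0.452 with an estimated correlation). NDUFA1 differed by 2.00 ± 0.16 among 24 of 33 oxidative phosphorylation genes that were higher, with NDUFB5, NDUFV2, SDHD, UQCRB and ATP5C1 lower (median 0.72, adjusted p = 3.8e-04, and adjusted p = 0.581 with an estimated correlation). MYC differed by 2.34 ± 0.14, CCNE1 by 0.99 ± 0.14, HSF1 by 0.70 ± 0.14, JUN by 0.65 ± 0.22 (adjusted p = 0.0176) and HSF2 by -1.11 ± 0.15. JUN was 0.22 (adjusted p = 0.370) without WT heat shock replicate 1, 0.21 (adjusted p = 0.380) without WT recovery replicate 1, 1.12 without WT heat shock replicate 2 or WT recovery replicate 2, and 0.61 (adjusted p = 0.0719) without KO heat shock replicate 1. It did not pass with DESeq2 (adjusted p = 0.0923), and with GC and length offsets neither JUN (0.20, adjusted p = 0.394) nor HSF1 (0.09, adjusted p = 0.507) did. BIRC3 had a lower response in KO cells (-2.84 ± 0.21), as did ERO1L (-1.91 ± 0.15) and SDHD (-1.64 ± 0.14). The list of FBXW7 substrate transcripts had 14 of 28 genes higher and 7 lower and did not pass (adjusted p = 0.165). For the histone list, which did not pass, the median (0.15) differs in sign from the test.

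In total 4979 genes had a higher and 4854 a lower response in KO cells, 2196 and 2397 of them by at least 1 on the log2 scale. Under upper-quartile scaling the split was 4417 higher and 5530 lower, and the median difference of all genes was -0.14. Of 4486 genes called in both lines, 3833 went in opposite directions (85.4%) and 653 in the same. These counts moved with the setting: 1456 of 1732 went in opposite directions without KO heat shock replicate 1, 1729 of 2063 without KO recovery replicate 1, 2573 of 2891 without KO heat shock replicate 2, 2644 of 2970 without KO recovery replicate 2, 2357 of 2654 with DESeq2, 2422 of 2737 at an adjusted p under 0.01 and 193 of 245 at a minimum fold change of 1.5 (78.8% to 89.0%). Genes that fell in WT and rose in KO cells numbered 2004, against 936 for independent lists, and those that rose in WT and fell in KO cells 1829, against 916. Those that rose in both numbered 314 and those that fell in both 339, against 893 and 960. Across 17471 genes, which are not independent replicates, the responses correlated at r = -0.29 and rho = -0.40. Single pairs of the same line correlated at 0.81 in WT and 0.65 in KO, and pairs of different lines at -0.25 to -0.22.

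**Figure D2:**
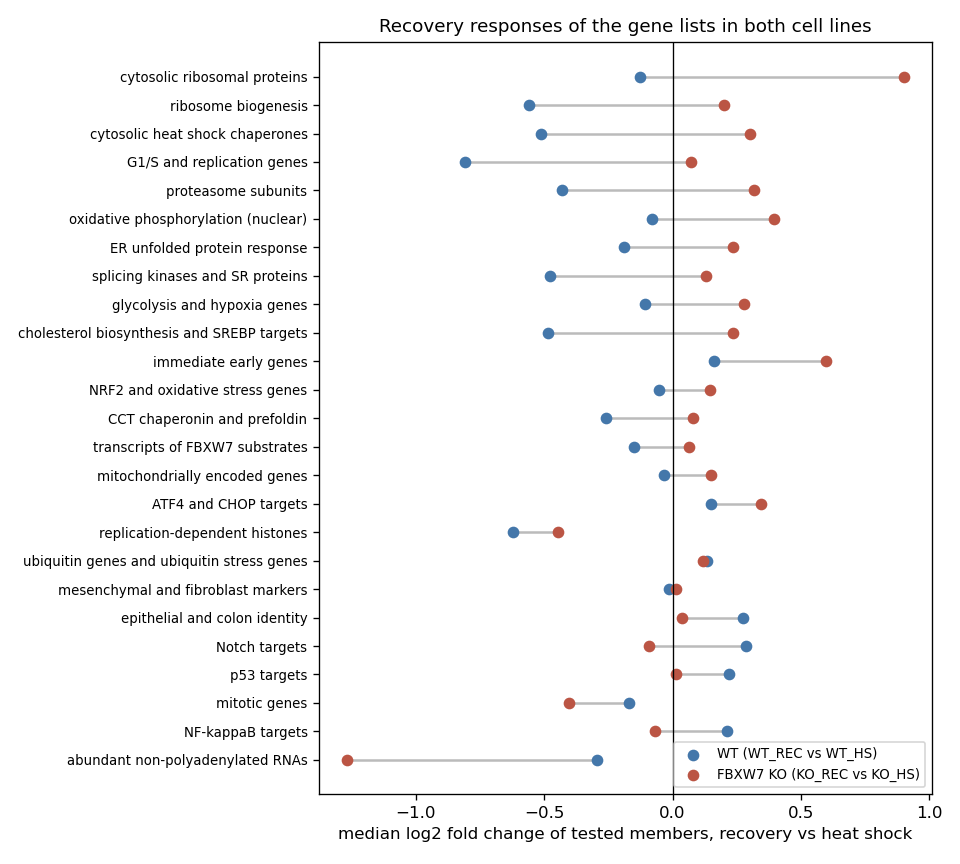
Median log2 fold change of each gene list between recovery and heat shock, on the horizontal axis, with WT in blue, KO in red and a grey line joining them. The chaperone list lies at -0.51 in WT and 0.30 in KO cells, and the ribosomal protein list at -0.13 and 0.90.

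KO and WT cells were next compared at the end of heat shock. PLK2, a p53-induced kinase, was higher in KO cells by 3.13 ± 0.09 (adjusted p = 1.1e-11), and NQO1, a quinone reductase and NRF2 target, lower by a log2 difference of -3.29 ± 0.09 (adjusted p = 9.5e-12). Targets of ATF4 and CHOP were lower: 23 of 27 were lower and 0 higher (25 and 0 adjusted over the list alone; median -0.88, adjusted p = 3.6e-13, and adjusted p = 0.123 with an estimated correlation). DDIT4 differed by -2.35 ± 0.08, TRIB3 by -1.99 ± 0.10, ASNS, asparagine synthetase, by -1.82 ± 0.10 and DDIT3 by -1.76 ± 0.12. Of 30 p53 targets 15 were higher and 4 lower (17 and 5 adjusted over the list alone; median 0.28, adjusted p = 0.00114, and adjusted p = 0.167 with an estimated correlation). SESN1 differed by 1.41 ± 0.13 and C12orf5, the TIGAR gene, by 1.37 ± 0.11, and the lower genes were GDF15 (-0.96 ± 0.09), TNFRSF10B, SERTAD1 and CYFIP2. The chaperone list as a whole did not pass at heat shock, with 15 of 38 genes higher and 9 lower (adjusted p = 0.704). HSPB1 was lower (-1.29 ± 0.11) and DNAJB4 higher (1.48 ± 0.13). Coding genes with transcripts of 600 to 1000 bases, a range that holds HSPB1 and DDIT3, had a median difference of -0.39. HSF1 differed by -0.75 ± 0.10, HSF2 by 0.61 ± 0.11, MYC by -1.19 ± 0.09, JUN by -1.14 ± 0.17 and CCNE1 by 0.67 ± 0.09. With GC and length offsets HSF2 did not pass (0.18, adjusted p = 0.0978).

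Mitotic genes were higher in KO heat shock, 27 of 38 against 2 lower, CCNB2 and AURKB, and the same adjusted over the list alone (median 0.50, adjusted p = 1.2e-07, and adjusted p = 0.391 with an estimated correlation). SGOL1, the protector of centromeric cohesion, differed by 1.27 ± 0.10, TTK, a spindle checkpoint kinase, by 1.10 ± 0.10 and KIF11 by 1.02 ± 0.09. Of 24 NRF2 and oxidative stress genes 15 were lower and GCLM, GCLC and PGD higher (15 and 4 adjusted over the list alone; median -0.42, adjusted p = 0.00114, and adjusted p = 0.392 with an estimated correlation). Of 30 glycolysis and hypoxia genes 19 were lower and SLC2A1, EGLN3, KDM3A and ERO1L higher (21 and 4 adjusted over the list alone; median -0.48, adjusted p = 0.00186, and adjusted p = 0.490 with an estimated correlation). ALDOC, an aldolase, differed by -2.07 ± 0.11 and NDRG1 by -1.45 ± 0.09. Of 52 ribosomal protein genes 43 were lower and RPL15, RPL22 and RPSA higher, the same adjusted over the list alone (median -0.95, adjusted p = 8.8e-22, and adjusted p = 0.391 with an estimated correlation), with RPS27 at -4.23 ± 0.18, RPLP0 at -2.03 ± 0.09 and RPS18 at -1.77 ± 0.09. Of 33 oxidative phosphorylation genes 19 were lower and 6 higher (21 and 6 adjusted over the list alone; median -0.32, adjusted p = 0.0117, and adjusted p = 0.541 with an estimated correlation), with COX6C at -2.14 ± 0.14. Beside both of these lists, 125 coding genes of 400 to 600 bases had a median of -0.61 and 18 under 400 bases one of 0.32, the share of mitochondrial tRNA was lowest in KO heat shock, and the kind of RNA these libraries were made from is not given in the sources used here.

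The epithelial and mesenchymal lists did not pass at heat shock, although single members differed between the lines. CLDN4, a tight junction claudin, differed by -2.41 ± 0.10, CLDN3 by -1.44 ± 0.15 and KRT18 by -1.13 ± 0.10, in an epithelial list with 7 of 13 genes lower and KRT20, VIL1 and AXIN2 higher (adjusted p = 0.0550). The median of this list was -0.24, and 0.08 with GC and length offsets. The transcription factor TWIST1 was higher by 1.95 ± 0.21, and the 9 mesenchymal markers had 3 higher (ZEB1, SNAI1 and TWIST1) and 2 lower (VIM and SPARC), or 4 and 3 adjusted over the list alone (adjusted p = 0.535). Among the largest differences, PODXL2 had 230 counts in the KO libraries and 0 in the WT libraries, at least 48.3-fold higher against a floor of 3 counts over the group. STC1, a secreted glycoprotein, was 144-fold higher with 2 counts in WT cells (95% counting interval 39.7 to 1193), and SPRR2D 81.6-fold higher with 3 counts (27.7 to 397). TM4SF18 (5.14 ± 0.36), STXBP6 (4.55 ± 0.30), TNFSF4 (3.90 ± 0.32), ZBED2 (3.69 ± 0.15), PDE4D (3.61 ± 0.18) and ANXA10 (3.32 ± 0.11) were higher, and ODZ3 (-5.04 ± 0.19), PROM2 (-4.23 ± 0.30) and ARAF (-3.58 ± 0.14), which overlaps SYN1, were lower. In total 4781 genes were higher and 4925 lower in KO cells, 1026 and 1560 at least 2-fold. Under upper-quartile scaling the split was 4323 higher and 5527 lower. For the immediate early list, which did not pass, median (0.02) and mean (-0.12) differ in sign.

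At recovery the KO libraries had higher levels of chaperone, ER unfolded protein response, ribosome biogenesis and cell cycle genes than the WT libraries. HSPA1B was higher by 3.97 ± 0.24 (adjusted p = 6.4e-09), DNAJA1 by 2.46 ± 0.10, DNAJB1 by 2.22 ± 0.15 and HSPH1, an HSP110, by 1.56 ± 0.11. Of 38 chaperone genes 31 were higher and BAG1, FKBP5 and ST13 lower, the same adjusted over the list alone (median 1.07, adjusted p = 4.7e-10, and adjusted p = 0.251 with an estimated correlation). Of 14 CCT chaperonin and prefoldin genes 12 were higher and 0 lower, the same adjusted over the list alone (median 0.37, adjusted p = 0.0300, and adjusted p = 0.511 with an estimated correlation), among them TCP1 (0.80 ± 0.09) and CCT7 (0.74 ± 0.09). This call failed under upper-quartile scaling (adjusted p = 0.0599), at a mean count of at least 50 (adjusted p = 0.127) and without KO recovery replicate 1 (adjusted p = 0.0530). Of 25 ER unfolded protein response genes 18 were higher and ERN1, ERO1LB and DERL1 lower, the same adjusted over the list alone (median 0.71, adjusted p = 7.4e-08, and adjusted p = 0.0787 with an estimated correlation). HERPUD1 differed by 2.91 ± 0.11, DNAJB9 by 2.11 ± 0.11 and MANF by 1.69 ± 0.09. HSF1 differed by -0.04 ± 0.10 (adjusted p = 0.729), HSF2 by -0.50 ± 0.11, MYC by 1.15 ± 0.09, JUN by -0.46 ± 0.17 (adjusted p = 0.0266) and CCNE1 by 1.66 ± 0.10. JUN did not pass without WT recovery replicate 2 (adjusted p = 0.191), KO recovery replicate 1 (adjusted p = 0.0719) or KO recovery replicate 2 (adjusted p = 0.116), and HSF1 passed with GC and length offsets (-0.28, adjusted p = 0.00243).

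Of 35 ribosome biogenesis genes 33 were higher and BOP1 lower, the same adjusted over the list alone (median 1.00, adjusted p = 2.2e-18, and adjusted p = 0.0807 with an estimated correlation), with GRWD1 at 2.46 ± 0.10 and NOP56 at 1.77 ± 0.08. Of 38 G1/S and replication genes 34 were higher and CCNE2 lower, the same adjusted over the list alone (median 0.87, adjusted p = 3.7e-14, and adjusted p = 0.202 with an estimated correlation), with CDC25A at 2.52 ± 0.10 and MCM10 at 1.67 ± 0.08. Of 38 mitotic genes 24 were higher and CENPE, CDC25C, HMMR and ASPM lower, the same adjusted over the list alone (median 0.36, adjusted p = 2.0e-04, and adjusted p = 0.308 with an estimated correlation), with PLK1 at 1.57 ± 0.11 and CCNB1 at 1.09 ± 0.08. Of 20 splicing genes 18 were higher and SRPK2 lower, the same adjusted over the list alone (median 0.79, adjusted p = 2.3e-07, and adjusted p = 0.0807 with an estimated correlation), with SRSF7 at 1.99 ± 0.14 and TRA2B at 1.48 ± 0.09. Of 32 proteasome subunits 28 were higher and 0 lower (29 and 0 adjusted over the list alone; median 0.71, adjusted p = 2.3e-07, and adjusted p = 0.305 with an estimated correlation), with PSMC5 at 1.20 ± 0.10. Of 29 cholesterol and SREBP genes 20 were higher and SQLE, CYP51A1, TM7SF2 and SCD lower (20 and 5 adjusted over the list alone; median 0.47, adjusted p = 0.00208, and adjusted p = 0.251 with an estimated correlation), with NSDHL at 1.58 ± 0.12. Of 41 immediate early genes 25 were higher and 8 lower, the same adjusted over the list alone (median 0.52, adjusted p = 3.3e-04, and adjusted p = 0.251 with an estimated correlation), with DUSP2 at 3.35 ± 0.14 and CYR61, a matricellular protein, at 2.21 ± 0.14.

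ATF4 and CHOP targets were lower in KO cells at recovery as well, 20 of 27 against ATF5 and CHAC1 higher (20 and 3 adjusted over the list alone; median -0.58, adjusted p = 1.4e-04, and adjusted p = 0.202 with an estimated correlation). DDIT4 differed by -2.20 ± 0.08, ASNS by -1.75 ± 0.10 and SLC7A11, the cystine transporter, by -1.27 ± 0.13. Epithelial identity genes were lower, 7 of 13 against KRT19, CDX2 and AXIN2 higher, the same adjusted over the list alone (median -0.32, adjusted p = 0.0161, and adjusted p = 0.251 with an estimated correlation). CLDN4 differed by -2.23 ± 0.09, CLDN3 by -1.96 ± 0.15, ESRP1, an epithelial splicing factor, by -1.82 ± 0.09 and CDH1, E-cadherin, by -1.30 ± 0.08. This list did not pass without the low-count filter (adjusted p = 0.209). Glycolysis and hypoxia genes had 9 of 30 higher and 14 lower, and their median of 0.01 differs in sign from their mean of -0.35 and from the test (adjusted p = 0.0494, and adjusted p = 0.610 with an estimated correlation). The call failed in 7 of 16 other settings, and the median was -0.16 under upper-quartile scaling. BNIP3L differed by -2.12 ± 0.10 and NDRG1 by -1.74 ± 0.09, whereas SLC2A1, the glucose transporter GLUT1, was higher by 1.69 ± 0.09. NQO1 differed by -3.37 ± 0.10, NOTCH3 by -1.58 ± 0.12 and NFATC2 by -3.42 ± 0.18. Ribosomal protein genes had 20 of 52 higher and 5 lower and did not pass (adjusted p = 0.138), with a median of 0.17 that was -3.2e-05 under upper-quartile scaling.

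PLK2 (3.91 ± 0.10) and BMP4, a secreted growth factor (4.26 ± 0.15), were among the genes most increased in KO recovery, with STXBP6 at 3.87 ± 0.32 and ZBED2 at 3.92 ± 0.14. PODXL2 was at least 45.4-fold higher against a floor of 3 counts over the group, with 199 KO counts and 0 WT counts. LARGE, a glycosyltransferase, was 513-fold higher with 1 count in WT cells (95% counting interval 91.9 to 20302), STC1 233-fold with 1 count (41.5 to 9218) and SPRR2D 169-fold with 3 counts (57.5 to 821). The 10 most decreased were pseudogenes such as ANXA2P2 (-5.56 ± 0.23), RPL3P4 (-5.49 ± 0.21) and EEF1A1P9 (-5.43 ± 0.16), apart from ZNF90, which overlaps one. In total 5562 genes were higher and 5464 lower, 1486 and 2611 of them at least 2-fold. Under upper-quartile scaling the split was 4212 higher and 6852 lower, and the median of all genes was -0.18. For the mesenchymal list, which did not pass, median (0.07) and mean (-0.18) differ in sign, and for the Notch list the median (-0.24) differs in sign from the test (adjusted p = 0.891).

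Both recovery responses followed transcript length and GC content. In WT recovery the median change of coding genes was -0.31 at 400 to 600 bases and 0.07 above 6000 bases, and it was 0.34 below 40% GC and -0.33 above 60% GC. In KO recovery the trends ran the other way, from 0.71 at 400 to 600 bases to -0.20 above 6000 bases and from -0.44 below 40% GC to 0.27 above 60% GC. The 18 coding genes under 400 bases lay off the length trends, with medians of -0.10 in WT and -0.02 in KO recovery. Their quartiles had both signs, -0.42 to 0.36 in WT and -0.23 to 0.65 in KO recovery. Coding genes of that length are of mixed kinds. They include RPS27, RPS21, the histone gene HIST1H2BK and the mitochondrially encoded MT-ND3 and MT-ND4L. Smooth trends on both properties had an r2 of 0.0274 to 0.303 in single libraries, set against the mean of all. The highest value was that of WT heat shock replicate 1, whose replicate 2 had 0.0787. KO heat shock replicates 1 and 2 had 0.204 and 0.157. WT heat shock replicate 1 enters WT recovery, the difference of responses and KO against WT at heat shock. With offsets that removed these trends 2623 of 3449 genes called in both lines went in opposite directions (76.1%). The offsets kept 4153 of the 7295 calls of KO recovery and turned 28, kept 6454 of the 9833 of the difference and turned 111, and kept 6658 of the 9706 between the lines at heat shock and turned 120.

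**Figure D3:**
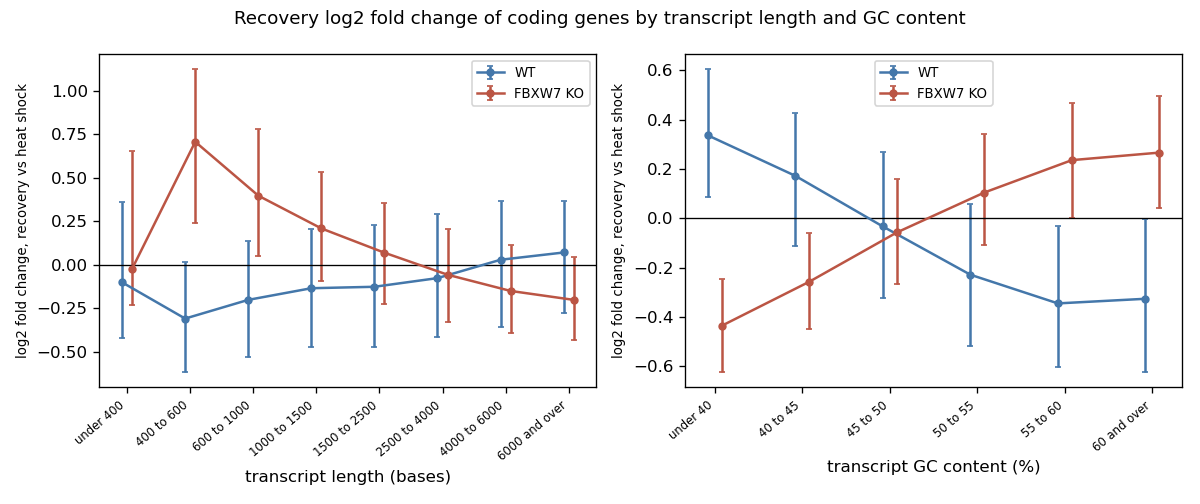
Median log2 fold change between recovery and heat shock of coding genes, by transcript length in bases (left) and GC content in percent (right), with bars from the lower to the upper quartile. In the bin of 400 to 600 bases the median is -0.31 in WT and 0.71 in KO cells, and under 400 bases (18 genes) it is -0.10 and -0.02.

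The authors' deposited tables, made from each replicate alone, gave for WT cells 5191 genes higher and 3031 lower at recovery with a q-value under 0.05 in both replicates. For KO cells the authors' deposited tables gave 2762 higher and 5174 lower. Of the 8874 WT calls made here 7064, and of the 7295 KO calls 6227, were also called in both replicates of the authors' deposited tables, with 0 in the opposite direction. Both sets of calls came from the same counts, so this is not independent evidence. At a q-value under 0.05 the 2 replicates called 173 genes in opposite directions in WT cells and 82 in KO cells. At a q-value under 0.001 and a fold change of at least 2, the authors' deposited tables held 889 higher and 175 lower genes in WT cells and 336 higher and 196 lower in KO cells. In the authors' deposited tables HSPA1B changed by -2.89 and -2.43 in the WT replicates and by 1.27 and 1.11 in the KO replicates on their log2 scale.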

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

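Of the tests in this part, those on short transcripts, on RNA selection, on GC content and length and on exchanged labels were chosen after the results had been seen, and those on pseudogenes were set before their values were known. Each result here differed between the lines by the test of the difference of their recovery responses, KO minus WT. That test called 9833 genes, and 3833 of 4486 genes called in both lines went in opposite directions, against 1456 of 1732 without KO heat shock replicate 1, 1729 of 2063 without KO recovery replicate 1, 2573 of 2891 without KO heat shock replicate 2, 2644 of 2970 without KO recovery replicate 2 and 2357 of 2654 with DESeq2. The median difference was 1.04 for chaperones, 0.43 for immediate early genes, 0.60 for the ER unfolded protein response, 1.05 for ribosome biogenesis and 0.50 for cholesterol and SREBP genes (adjusted p = 0.452 each with an estimated correlation). It was 0.93 for G1/S and replication genes, 0.79 for proteasome subunits, 0.59 for splicing genes, 1.11 for ribosomal proteins and 0.72 for oxidative phosphorylation. With an estimated correlation these had an adjusted p of 0.581 for proteasome subunits and oxidative phosphorylation and 0.452 for the others, so none of the lists passed. With GC and length offsets the immediate early list did not pass (adjusted p = 0.0596) and its median was -0.04. Of the regulators reported in each comparison, the difference was 0.70 for HSF1, -1.11 for HSF2, 2.34 for MYC, 0.65 for JUN and 0.99 for CCNE1. JUN was 0.22 without WT heat shock replicate 1 and 0.21 without WT recovery replicate 1, where it did not pass, 1.12 without WT heat shock replicate 2 or WT recovery replicate 2, and did not pass without KO heat shock replicate 1. With GC and length offsets neither JUN (0.20) nor HSF1 (0.09) passed.

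Among single genes the response was higher in KO cells for OVOL3 (7.60), WDR38 (6.79), MTND1P23 (6.58), FAM166A (5.04), SNHG9 (4.93), RPS28 (4.53), PHOX2A (4.38), RPS27 (4.28), HSPA1B (4.12) and CSDC2 (3.85). It was lower for PPIAP22 (-7.35), EEF1A1P6 (-6.66), EEF1A1P11 (-6.08), GAPDHP63 (-6.06), EEF1A1P5 (-5.73) and ANXA2P2 (-5.41). It was also lower for EDARADD (-5.34), ENO1P1 (-5.31), FAM3C2 (-5.26) and SCDP1 (-5.26). Apart from RPS27 and HSPA1B, which has the near-identical copy HSPA1A, the genes in the first group overlap or adjoin an expressed gene or are a copy of one, among them CSDC2, which overlaps PMM1. In KO recovery the neighbours POLR2I, RPL35, TUBB4B, RPS2, NDUFA7, INPPL1 and PMM1 changed by 0.11 to 1.70, less than the genes beside them. The share of the neighbours' reads in the counts of these genes was not measured.

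For the opposite recovery responses of the chaperone list in WT and KO cells, GC content and length trends as the whole cause are argued against by the mean difference of the list, which was 1.04 (SE 0.165) with offsets that remove those trends and 1.08 (SE 0.192) without them, with errors taken over genes as if independent. Camera's adjusted p with the offsets was 4.3e-16, but 0.377 with an estimated correlation. KO libraries correlated with WT libraries of the unlike condition at a mean r of 0.954 and with those of the like condition at 0.947, -0.0073 apart, where KO recovery with WT heat shock gave 0.972, KO heat shock with WT recovery 0.936, KO heat shock with WT heat shock 0.959 and KO recovery with WT recovery 0.934, so that KO recovery lay closer to the unlike condition and KO heat shock to the like one. The mean gap is what an exchange of heat shock and recovery labels in 1 of the lines predicts. It slightly exceeded the largest difference in r between replicates, 0.0071. Each WT group also correlated at least as well with the KO group of the unlike condition, though for WT recovery by less than that difference. Such an exchange and a genuine difference between the lines cannot be told apart, since the design gives both the same libraries. A different recovery in the KO line, where FBXW7 counts were lower but not absent, may underlie the pattern and stays open, untested, as do other differences between the cell lines.

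Transcripts of 400 to 1000 bases were low in the 2 KO heat shock libraries. The 18 coding genes under 400 bases had a median difference from WT of 0.32 (quartiles -0.74 to 0.56). With so few genes and quartiles of both signs, they cannot speak for or against a loss of short transcripts. Such a loss may account for coding genes of 400 to 1000 bases outside the ribosomal protein list, where the median difference from WT was -0.41 over 725 genes of 400 to 1000 bases and 0.09 over 6880 genes above 2500 bases, -0.504 apart. For ribosomal protein genes such a loss may not be the whole cause. They lay below genes matched on length, GC content and level by a median of -0.337 (95% interval -0.594 to -0.130), 34 of 52 being below their matches. That interval takes genes as independent, but their estimated correlation was 0.347, with which camera gave the list an adjusted p of 0.391, so it is too narrow to decide. A different RNA selection in those libraries, poly-A or ribosomal RNA depletion, cannot be told apart from such a loss: nuclear non-polyadenylated RNAs had a median difference of 1.16 (95% interval -0.376 to 1.88, 10 RNAs) and mitochondrial tRNAs of -1.52 (-2.61 to 0.401, 21 RNAs). Whether anything else lowered the ribosomal protein transcripts stays open, and a biological difference by genotype was not tested.

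Processed pseudogenes were high in the 2 WT recovery libraries, where 264 of 367 with a named parent rose and 10 fell, with a median of 2.92 against -0.07 for the parents. Over 2834 genes, of which 1806 were lincRNA or antisense genes of any level and the others low-level coding genes, the median change was 0.15 (SE 0.0230). This argues against a rise of such genes as large as that of the pseudogenes, but added background would shift well-expressed members less. The WT recovery libraries had reads for 24139 and 24307 genes, against 22935 and 22944 in WT heat shock, at fewer total counts. Genomic DNA in those libraries is therefore not excluded. Assignment of parent reads to pseudogenes stays possible: pseudogenes of parents above the median level had a median change of 3.02 and those of lower parents 2.24, and the gap of 0.781 had a 95% interval of -0.192 to 1.82. That interval is too wide to decide, so this cannot be told apart from other sources, and a biological rise of the pseudogenes was not tested.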

How the results depend on the processing

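The settings with GC and length offsets, with long coding genes alone and without the pseudogene on the mitochondrially encoded list were chosen after the data had been seen, and the others before. A minimum fold change of 1.5 left 2261 genes in WT recovery, 1005 in KO recovery, 4989 in the difference, 2878 between the lines at heat shock and 4752 at recovery, since it asks for more than a change, and FBXW7 at recovery (-0.68) did not pass it (adjusted p = 0.193). DESeq2 called 4789 genes in KO recovery. Leaving out each library in turn gave 6563 to 8699 genes in WT recovery, 2838 to 8244 in KO recovery, 7640 to 9622 in the difference, 7873 to 9942 between the lines at heat shock and 9012 to 12052 at recovery. The lowest KO recovery counts were without KO heat shock replicate 1 (2838) and KO recovery replicate 1 (3245), where fewer libraries were compared and a lone library is assumed to vary like the other groups. With camera at an estimated correlation 0 lists passed in all 5 comparisons, against 2, 3, 2, 3 and 5 at an unadjusted p under 0.05, and 9, 12, 10, 7 and 13 passed at the preset one. Fry passed 9, 9, 12, 17 and 19. Between the lines at heat shock the offsets gave 11 lists under both transcript definitions, and the cause was not tested. The correlation of the responses was -0.27 with the offsets, -0.35 in long coding genes, -0.34 at a mean count of at least 50 and between -0.251 and -0.243 without 1 library, against -0.29. The authors' deposited tables held 1064 genes in WT and 532 in KO cells at the stricter threshold. JUN in WT recovery changed sign with the replicate pair left out, at 0.39 without WT heat shock replicate 1, 0.40 without WT recovery replicate 1 and -0.51 without WT heat shock replicate 2. The replicate block changed little: without it the recovery comparisons gave 9045, 7399 and 9999 genes, with a block shared by both lines 9003, 7387 and 9967, and the comparisons of the lines with a replicate block 9656 and 11013. With the offsets 28 genes called in KO recovery, 111 in the difference and 120 between the lines at heat shock turned direction, and 4153 of 7295, 6454 of 9833 and 6658 of 9706 calls were kept. Of 125 list medians the offsets changed the sign of 12, 2 of them of lists past the threshold: immediate early genes in the difference (0.43 to -0.04) and glycolysis and hypoxia genes between the lines at recovery (0.01 to -0.12). Upper-quartile scaling also changed 12 of 125, RLE scaling 1 of 125 and long coding genes 17 of 110. Over named genes and the tests of single lists, other settings kept the side of the threshold in 7856 cases and lost a call in 324. They gained a call in the same direction in 100 and gave a call in the opposite direction in 0. Leaving out a library did so in 5683, 153, 38 and 2. Direction was compared only where the other setting gave a call, so lost calls and results not called in either fit may have changed sign. Counts of 3 or fewer in WT cells limit the folds of PODXL2, STC1, SPRR2D and LARGE.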

Other observations

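The counts of genes shared between conditions and the choice of ubiquitin genes in this part were made after the results had been seen. Differences between KO and WT cells were in part shared by both conditions. Higher levels in KO cells were called at heat shock and at recovery for 1902 genes, against 1522 for independent lists. Lower levels in both were called for 1745, against 1540. Another 2720 genes went in opposite directions, and no number for independent lists was computed for them, so they do not show a reversal beyond such lists. Across genes the differences correlated at r = 0.28 and rho = 0.15. At least 2-fold in both were 255 higher and 524 lower genes. PLK2 was higher by 3.13 ± 0.09 at heat shock and 3.91 ± 0.10 at recovery, and TM4SF18, STXBP6 and ZBED2 were among the 10 largest in both. NQO1 was lower in both conditions (-3.29 ± 0.09 and -3.37 ± 0.10), as were CLDN4 (-2.41 ± 0.10 and -2.23 ± 0.09), DDIT4 (-2.35 ± 0.08 and -2.20 ± 0.08), ASNS (-1.82 ± 0.10 and -1.75 ± 0.10) and NDRG1 (-1.45 ± 0.09 and -1.74 ± 0.09).

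Of 14 ubiquitin genes 6 rose and 5 fell in WT recovery, and 7 rose and 3 fell in KO recovery. Their list did not pass in any of the 5 comparisons. ZFAND2A, induced by arsenite and heat, fell by 1.49 ± 0.20 in WT cells and rose by 1.40 ± 0.16 in KO cells, a difference of 2.90 ± 0.26. NBR1, an autophagy receptor, was lower in KO recovery than in WT recovery by a log2 difference of -1.35 ± 0.08. Under GC and length offsets the median of the ubiquitin list in WT recovery was -0.03, against 0.14 without them. The DUSP2, EGR1 and HERPUD1 transcripts differed in the responses by 3.30 ± 0.20, 2.68 ± 0.15 and 3.46 ± 0.14, beside 4.12 ± 0.16 for HSPA1B.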
